A study of Saccharomyces cerevisiae W303 with 8 samples.

How the data were processed

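Footprints were counted in 8 libraries of Saccharomyces cerevisiae W303, 2 for each of 4 carbon sources, grouped by the carbon source and replicate number in the sample titles. Per the labels' protocols, total RNA was extracted with a Direct-zol kit and libraries were made with a NEBNext small RNA kit. Per the submitters' processing notes, Trimmomatic 0.39 and Bowtie 1.2.3 were used with genome build R64, and the settings are not given in the sources used here. The authors deposited a workbook with a sheet per library, and each sheet was matched to its sample by the sheet's name, since all sheets have the same columns. Per the file headers, each sheet lists reference sequences with a length, mapped reads and unmapped reads. The mapped reads are whole-number counts, deposited without normalization, and the unmapped reads are 1 count per library. The reference length is in bases. In each sheet 4 lines were empty.

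Of the 6718 reference sequences, 6036 were named by locus tag through a RefSeq table of assembly R64, and the 682 others held 0.06% of the counts. For 6013 named genes the reference was 2000 bases longer than the gene, which fits 1000 bases on each side. A count can therefore include reads outside the gene. Zeros went with these flanks: of 1169 genes with no base outside the flanks of other genes on the same strand, 80.2% were at 0 in all libraries, against 4.7% of 4432 genes with over 200 such bases. In all, 1220 of 6018 named protein-coding genes were at 0 in every library, and a count of 0 for such a gene says nothing about its translation. Genes with near-identical copies, among them many ribosomal protein pairs and hexose transporters, can lose reads or share them in the same way, so the values of single paralogs are uncertain. The share of 28-base windows that a gene has in common with others was to be checked in naming genes, but no genome was used here and this check was not run.

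Library totals ranged from 184589 to 909504 counts. In a single library, before TMM scaling, 3 counts stood for 14.2 and 13.9 CPM on glucose and 3.30 CPM in glycerol replicate 1. Where a group had 0 counts, the floor used was 3 counts over both its libraries together, a lower level in CPM. Intervals and floors cover counting error only, since reads are not known to be independent molecules. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. That spread is estimated over all 8 libraries together, so glycerol's wider spread enters every comparison. The common dispersion, edgeR's measure of spread between replicates, was 0.0188 for glucose, 0.0288 for galactose, 0.144 for glycerol and 0.0195 for trehalose. Over all 8 libraries it was 0.0657. No pair of replicates agreed within sampling noise: chi-square per degree of freedom was 6.77 for glucose, 7.29 for galactose, 53.0 for glycerol and 4.78 for trehalose, and all libraries were kept as separate replicates.

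Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (3209 genes), libraries scaled by TMM, and a quasi-likelihood F test fitted to all 8 libraries with a term per carbon source, with 4 residual degrees of freedom. Each pair of carbon sources was compared, and all 4 were compared in a test with 3 degrees of freedom. Calls are at a Benjamini-Hochberg adjusted p under 0.05, and fitted fold changes use a prior count of 0.125. CPM are counts scaled by the TMM-adjusted library total, and the SE is the size of the log2 fold change over the square root of F. Of genes with 0 counts in a group the fold is a bound against 3 counts over the group, and with 1 to 3 counts it is the ratio of counts with an exact 95% interval.

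Before the data were examined, 35 gene lists were fixed, of pathways, complexes and cell type markers. The 31 lists with at least 3 tested genes were tested against glucose with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts of genes that rose or fell are out of a list's tested members only. These were 88 of 138 for ribosomal proteins, 11 of 24 for the respiratory chain, 7 of 14 for ATP synthase and 5 of 18 for hexose transporters. Shares of lists are percents of each library's counts. Genes were named by a rule fixed at the same time: the 6 largest rises and falls against glucose (4 in other comparisons) among called genes with at least 20 CPM in the higher group and replicates that do not overlap, up to 4 called members of each list by size of change, or the member with the smallest p where none was called, and a fixed set of 30 genes.

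The procedure was tested on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes. Of 2-fold changes 6% were recovered for galactose against glucose, 16% for glycerol and 9% for trehalose, and of 4-fold changes 70%, 80% and 66%, with 5, 1 and 6 false calls among 3070, 3061 and 3057 genes tested. Changes of 2-fold in single genes were therefore mostly missed in this simulation. More genes passed in the data than were changed in it (241, 743 and 1189 against 200), so recovery in the data may differ. On trehalose 551 of the 600 genes higher and 495 of the 589 lower were over 2-fold, so some smaller changes were called. The simulation gave every carbon source the same dispersion, so it cannot show how glycerol's wider spread affects recovery or false calls. Alternatives were the scaling, the filter on low counts, DESeq2 1.42.0, limma-voom, robust estimation, a minimum fold change, the libraries in the fit, a block for the replicate number, and leaving out each library in turn.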

Results

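Ribosome footprints, the short mRNA fragments that translating ribosomes protect from nuclease, were counted per gene in the budding yeast Saccharomyces cerevisiae (strain W303) grown on glucose, galactose, glycerol or trehalose. Each carbon source had 2 libraries, 8 in all. The total counts were 210576 and 215436 for glucose, 184589 and 319651 for galactose, 909504 and 436717 for glycerol, and 723305 and 211309 for trehalose, replicate 1 first, a 4.93-fold range. The design text names transcription and translation in 4 growth conditions as the subject of the study. The question put here is which genes took a larger or smaller share of the footprint counts on each carbon source. These counts can include reads on the flanks of each reference sequence and are not limited to the coding sequence. A count is a share of all footprints in its library and holds no amount per cell. The RNA-seq libraries that the design text mentions are not analysed here, so no translational efficiency is given.

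Libraries of the same carbon source were close to each other for 3 of the 4 carbon sources. Between replicates, the biological coefficient of variation was 0.137 for glucose, 0.170 for galactose and 0.140 for trehalose, and 0.380 for glycerol. Glycerol replicate 2 had a Spearman correlation across genes of 0.85 with glycerol replicate 1 and of 0.929 with trehalose replicate 1. The 2 trehalose libraries had 0.922 with each other. Galactose replicate 2 had 0.912 with galactose replicate 1 and 0.92 with glycerol replicate 1. Genes are not independent replicates, so these correlations carry no test. Every library was kept under its label, though a wrong label of glycerol replicate 2 stays open.

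**Figure D1:**
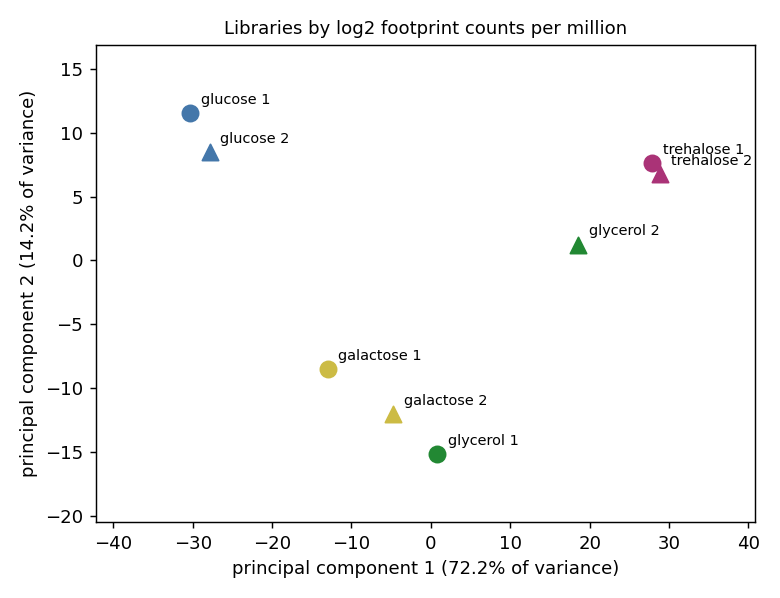
Principal components 1 and 2 (72.2% and 14.2% of the variance) of log2 footprint CPM, a point per library, coloured by carbon source, circles for replicate 1 and triangles for replicate 2. Glycerol replicate 2 lies at 18.6 on component 1, between glycerol replicate 1 at 0.763 and the trehalose libraries at 27.8 and 28.9.

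Across the 4 carbon sources, 955 of 3209 genes tested differed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Without glucose replicates 1 and 2 in turn this count was 347 and 424, without trehalose replicates 1 and 2 it was 479 and 568, and without glycerol replicates 1 and 2 it was 1495 and 1608. The cytosolic ribosomal proteins took 12.2% ± 0.631 of all footprint counts on glucose, 6.11% ± 0.0931 on galactose, 6.15% ± 1.46 on glycerol and 4.07% ± 0.104 on trehalose (mean ± SD, n = 2). The ribosome biogenesis genes, whose products assemble ribosomes, took 2.71% ± 0.0871, 1.70% ± 0.242, 1.40% ± 0.19 and 1.14% ± 0.0611 in the same order. Amino acid biosynthesis genes controlled by the transcription factor Gcn4 took 3.51% ± 0.0776 on glucose and 1.32% ± 0.0369 on trehalose, and the glycogen metabolism genes took 0.0230% ± 0.00104 on glucose and 0.232% ± 0.0312 on trehalose. General stress response genes took 0.335% ± 0.0553 on glucose, 0.827% ± 0.0105 on galactose, 1.51% ± 1.11 on glycerol and 3.11% ± 0.104 on trehalose. Glycolysis and ethanol formation took 11.7% ± 0.23 on glucose and 8.69% ± 0.222, 8.62% ± 1.81 and 10.3% ± 0.0306 on galactose, glycerol and trehalose.

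An exact permutation test of the F statistic over the 105 partitions of the libraries into 4 pairs, adjusted over 35 lists, called 8 lists, each at the smallest p the design allows, 0.009524, with an adjusted p of 0.0417. These were the Gcn4 targets, glycogen metabolism, trehalose synthesis and breakdown, glycerol synthesis, peroxisomal beta-oxidation, the iron uptake regulon, and the haploid and the meiosis and sporulation markers. No meiosis and sporulation marker had enough counts to be tested singly, and the most, in SSP1, were 89 over all 8 libraries. The ribosomal protein and ribosome biogenesis shares did not pass (adjusted p = 0.0625 and 0.0606), nor did general stress (0.0625), glycolysis (0.0933) or the respiratory chain (0.119), all by the same exact permutation test. Without glycerol replicate 1 the test called 24 lists and without glycerol replicate 2 it called 25, while leaving out any other library, of glucose, galactose or trehalose, left 0. Even at the smallest p, a list passes only where several of the 35 lists reach that p together. Lists can therefore drop out together, and a list that was not called may still differ. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333 and was not run on shares.

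**Figure D2:**
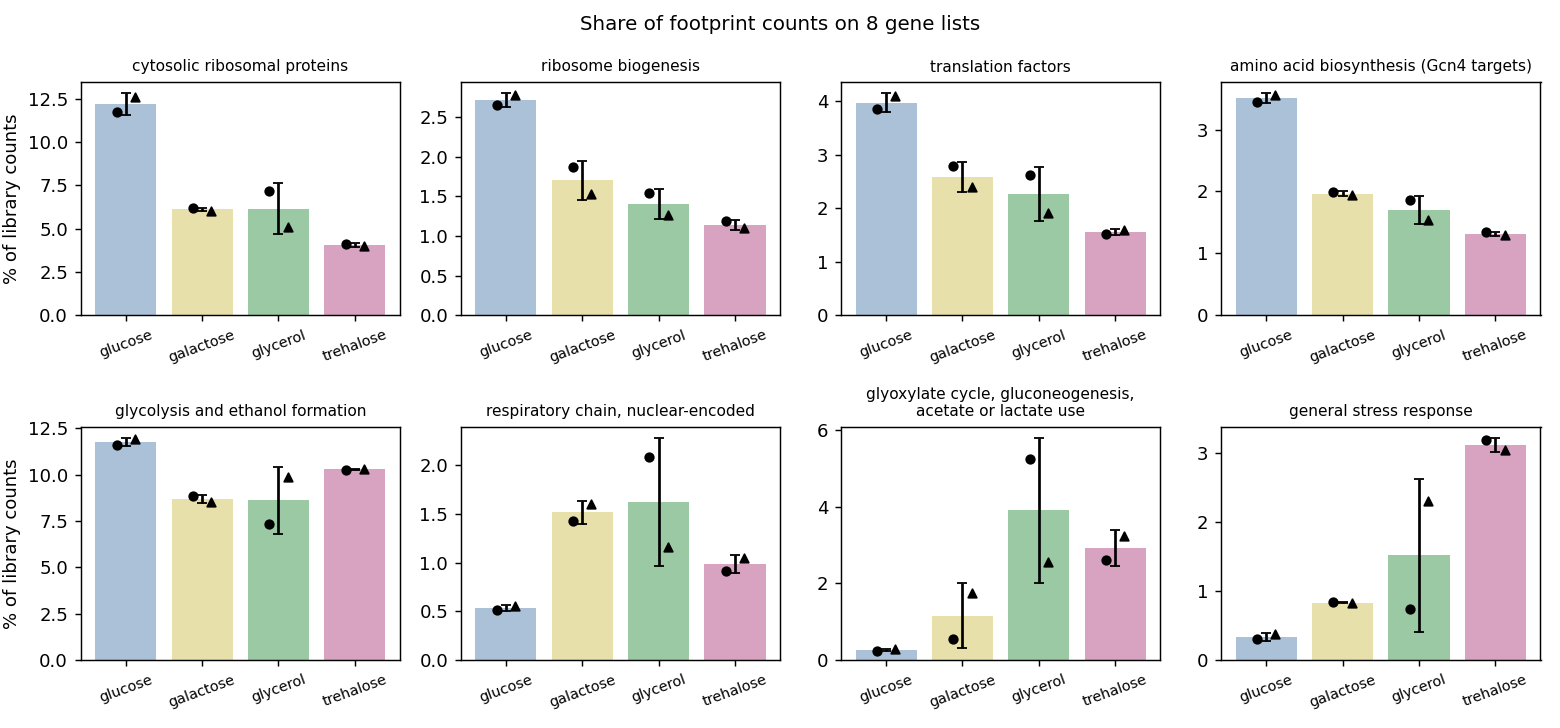
Percent of each library's footprint counts that fell on 8 gene lists, by carbon source. Bars start at 0 and give the mean of 2 libraries, error bars the SD, and black points the libraries (circle, replicate 1; triangle, replicate 2). The ribosomal protein share was 12.2% on glucose and 4.07% on trehalose, and glycerol's libraries lie far apart in the panels for the respiratory chain and general stress.

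Growth on galactose was compared with growth on glucose to ask which genes' translation differs between these fermentable hexoses. The galactose pathway was higher on galactose: 5 of its 6 tested genes rose and 0 fell, 5 and 0 also when adjusted over the list alone (camera adjusted p = 2e-10; adjusted p = 0.0417 with an estimated correlation). Footprints of GAL2 (YLR081W, chromosome XII, 290212 to 291936, build R64), the galactose permease, went from 453 ± 159 to 8147 ± 124 CPM (counts scaled to the library total; SD, n = 2), a log2 fold change of 4.17 (SE 0.577, adjusted p = 0.00672). GAL10 (YBR019C, chromosome II, 276253 to 278352), an epimerase of the pathway, rose by 3.64 (SE 0.539) and GAL7 (YBR018C), the uridylyltransferase beside it, by 3.44 (SE 0.496) on the log2 scale. Without glucose replicate 2 GAL10 was at 4.35, not past the threshold, and GAL7 at 4.34. PGM2, a phosphoglucomutase, rose by 2.87 (SE 0.360). GAL1, the galactokinase gene, had 0 counts in all 8 libraries, galactose included, and was not tested.

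Glucose-associated hexose transporters were lower on galactose, 4 of 5 tested having fallen and 0 risen (4 and 0 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation). HXT1 (YHR094C, chromosome VIII, 290913 to 292625), a low-affinity transporter, went from 240 ± 65.5 to 14.5 ± 2.28 CPM, a log2 fold change of -4.05 (SE 0.525), and HXT3 (YDR345C) changed by -3.64 (SE 0.441). HXK1, a hexokinase, rose by 2.80 (SE 0.434), and PDC1, the main pyruvate decarboxylase, fell by 1.46 (SE 0.277) on the log2 scale. These were the only 2 of the 19 tested genes of glycolysis and ethanol formation to pass the test (3 rose and 3 fell adjusted over the list alone), and that list did not shift (camera adjusted p = 0.593; its median was -0.28 and its mean 0.08). CDC19, pyruvate kinase, had a log2 fold change of -0.65 (SE 0.236, adjusted p = 0.130) and HXK2 of 0.57 (SE 0.251, adjusted p = 0.208).

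Genes of the iron uptake regulon included FIT3, with the largest rise that the naming rule gave, and had 6 of 12 tested genes risen and 0 fallen (7 and 0 adjusted over the list alone; adjusted p = 0.0878 with an estimated correlation). FIT3 (YOR383C, chromosome XV, 1060441 to 1061055), a cell wall mannoprotein that retains iron-binding siderophores, went from 49.2 ± 1.30 to 1445 ± 97.8 CPM, a log2 fold change of 4.87 (SE 0.301, adjusted p = 5.37e-05). Its neighbour FIT2 rose by 4.04 (SE 0.391), ARN2, a siderophore transporter, by 3.26 (SE 0.621), and TIS11, an mRNA-binding protein of iron starvation, by 2.75 (SE 0.387). FIT2 was at 4.70 without glucose replicate 2 and ARN2 at 2.48 without galactose replicate 1. ARN2 did not pass when any 1 of the glucose or galactose libraries was left out (highest adjusted p = 0.186).

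Respiratory functions were higher on galactose. Of 11 tested nuclear-encoded genes of the respiratory chain 8 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), with NDI1, the internal NADH dehydrogenase, at a log2 fold change of 2.22 (SE 0.346) and QCR2 at 1.62 (SE 0.310). In the TCA cycle 7 of 13 rose and 0 fell (12 rose and 1 fell adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), and CIT1, citrate synthase, went from 487 ± 8.01 to 2392 ± 57.2 CPM, a log2 fold change of 2.29 (SE 0.300). Glycogen metabolism had 4 of 7 risen (6 adjusted over the list alone; adjusted p = 0.0417 with an estimated correlation), with GPH1, glycogen phosphorylase, at 2.65 (SE 0.421). Of 5 glycerol uptake and catabolism genes 3 rose (4 adjusted over the list alone; adjusted p = 0.0878 with an estimated correlation), among them GUT1, glycerol kinase. Genes of the glyoxylate cycle and gluconeogenesis rose in 4 of 19 cases (11 adjusted over the list alone; adjusted p = 0.292 with an estimated correlation). Their galactose libraries differed: ADH2, alcohol dehydrogenase 2, had 988 CPM in galactose replicate 1 and 5496 in replicate 2 (log2 fold change 2.23, SE 0.694, adjusted p = 0.0817), and PCK1 had 183 and 734 CPM (2.75, SE 0.737, adjusted p = 0.0509).

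The translation machinery was lower on galactose. Of 88 tested cytosolic ribosomal protein genes 42 fell and 0 rose (68 and 0 adjusted over the list alone), with a median log2 fold change of -1.14 (camera adjusted p = 4.78e-32; adjusted p = 0.0417 with an estimated correlation). RPL20A changed by -1.68 (SE 0.315) and RPS3 by -0.99 (SE 0.257), whereas RPL3, at -0.85 (SE 0.268), did not pass (adjusted p = 0.0859). Of 106 ribosome biogenesis genes 10 fell and 0 rose (20 and 0 adjusted over the list alone; adjusted p = 0.114 with an estimated correlation), among them NSR1, a nucleolar protein, at -1.45 (SE 0.262). Of 28 translation factors 4 fell (7 adjusted over the list alone; adjusted p = 0.234 with an estimated correlation), TEF4 at -1.15 (SE 0.241). Of 35 Gcn4 targets 12 fell and 0 rose (18 and 0 adjusted over the list alone; adjusted p = 0.0417 with an estimated correlation), with ARG3, of arginine synthesis, at -2.74 (SE 0.294).

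In all, 241 genes passed in this comparison, 128 higher and 113 lower on galactose, and 744 genes had an unadjusted p under 0.05. Without both glycerol libraries, whose spread enters the shared estimate, 617 genes passed, and 240 of the 241 were among them. The gene lists shifted in 23 of 31 cases with camera's preset correlation, and in 5 with an estimated correlation. The count fell when any 1 of the glucose, galactose or trehalose libraries was left out, and rose without either glycerol library. A fit without a glucose or galactose library has 1 library for that carbon source. A lower count there includes a loss of power and does not single out a library. Of the 74 named genes that passed, FIT3 was the only 1 past the threshold in all 8 fits that left out a library. The fold change of 17 of the 74 moved by over 1.5 times on leaving out some library: 3 and 7 without glucose replicates 1 and 2, and 4 and 8 without galactose replicates 1 and 2.

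**Figure D3:**
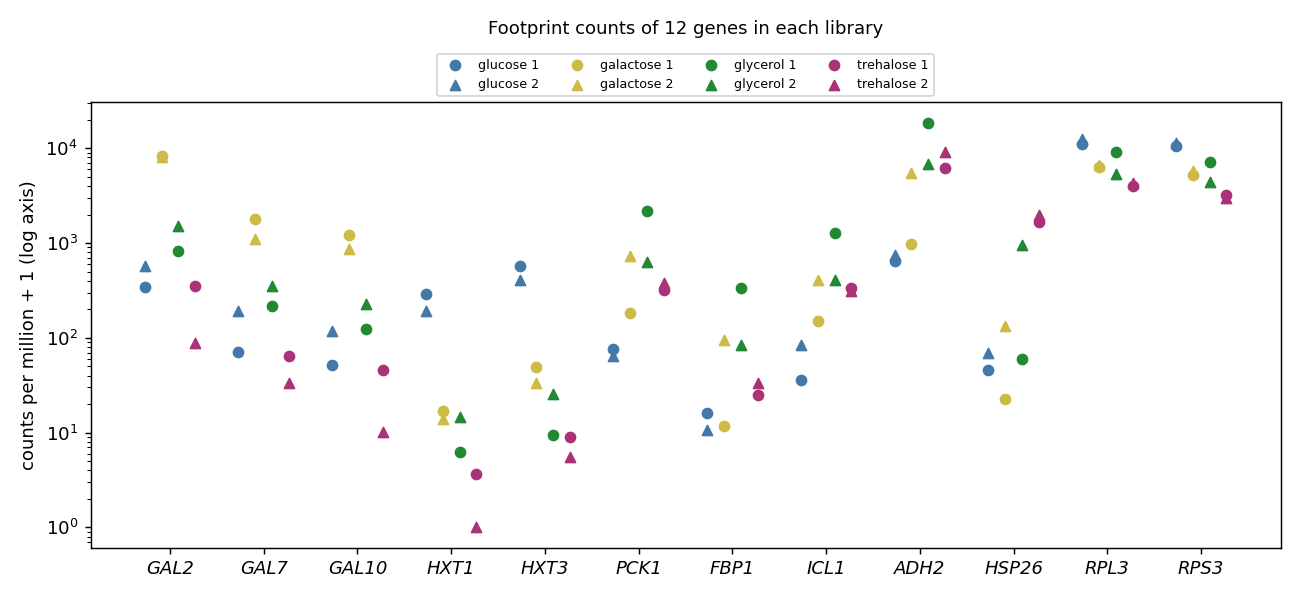
Footprint CPM plus 1 (log axis) of 12 genes in each of the 8 libraries, coloured by carbon source, circles for replicate 1 and triangles for replicate 2. GAL2 stands at 8234 and 8060 CPM in the galactose libraries and HXT1 at 286 and 193 CPM in the glucose libraries, while PCK1, ADH2 and HSP26 differ between the glycerol libraries.

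Growth on glycerol was compared with growth on glucose to ask which genes' translation differs on a non-fermentable carbon source. Glycerol catabolism was higher: 4 of 5 tested genes rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.0870 with an estimated correlation). GUT1 went from 59.0 ± 5.40 to 878 ± 524 CPM (log2 fold change 3.89, SE 0.580, adjusted p = 0.00319), GUT2, the mitochondrial glycerol-3-phosphate dehydrogenase, from 144 ± 55.4 to 1134 ± 280 CPM (2.97, SE 0.400), and STL1, the glycerol-proton symporter, from 31.8 ± 16.6 to 333 ± 230 CPM (3.39, SE 0.605). Without glycerol replicate 1 GUT1 was at 3.10 and STL1 at 2.40, and without glucose replicate 2 STL1 was at 4.04.

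Genes for growth without sugar were higher on glycerol. In the list of the glyoxylate cycle, gluconeogenesis and acetate or lactate use, 18 of 19 tested genes rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 3.83 (camera adjusted p = 1.35e-15; adjusted p = 0.180 with an estimated correlation). CAT2, carnitine acetyltransferase, rose by 4.95 (SE 0.689), PCK1 by 4.35 (SE 0.750), ADH2 by 4.21 (SE 0.750), FBP1, fructose-1,6-bisphosphatase, by 4.09 (SE 0.980) and ICL1, isocitrate lyase, by 3.82 (SE 0.668) on the log2 scale. Glycerol replicate 1 held 2187 CPM of PCK1 and glycerol replicate 2 held 635. Without glycerol replicate 1 PCK1, ADH2, FBP1 and ICL1 were at 3.20, 3.32, 2.72 and 2.76, each over 1.5 times smaller in fold. Without glycerol replicate 2 PCK1, FBP1 and ICL1 were at 4.99, 4.73 and 4.42, and ICL1 was at 4.55 without glucose replicate 2. FBP1 did not pass without glucose replicate 1 or 2 (higher adjusted p = 0.112). Peroxisomal beta-oxidation had 10 of 11 genes risen and 0 fallen (10 and 0 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation), POX1 at 4.49 (SE 0.579) and FOX2 at 3.59 (SE 0.479). Its gene DCI1 had 0 counts on glucose and was at least 6.74-fold higher on glycerol, against a floor of 3 counts over the group. The median of that list was 3.35, and 3.09 with DCI1 at its bound.

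Of the 24 respiratory chain genes listed 11 were tested, and all 11 rose (11 adjusted over the list alone, adjusted p = 0.164 with an estimated correlation). CYB2, a lactate dehydrogenase, was at 3.67 (SE 0.592, and 2.78 without glycerol replicate 1) and NDI1 at 2.18 (SE 0.343). Those not tested include COX4, COX5A, COX6, COX7 and COX8, with 0 counts in every library. In the TCA cycle 11 of 13 genes rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.294 with an estimated correlation). CIT1 changed by 2.71 (SE 0.303), and CIT3, with 0 counts on glucose, was at least 12.6-fold higher. The fitted log2 value of CIT3, which depends on the prior count, was 8.10, and 7.04 without glycerol replicate 1. Of 7 tested ATP synthase genes 5 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.365 with an estimated correlation), ATP18 by 1.85 (SE 0.335) and ATP1 by 1.27 (SE 0.286).

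Storage carbohydrate and stress genes were higher. Of 21 general stress genes 15 rose and 0 fell (19 and 0 adjusted over the list alone; adjusted p = 0.314 with an estimated correlation), including CTT1, cytosolic catalase, at 4.29 (SE 1.05). The list's share of counts was 0.731% in glycerol replicate 1 and 2.30% in replicate 2, against 0.835% and 0.820% in the galactose libraries. CTT1 had 108 CPM in glycerol replicate 1 and 1073 in replicate 2. Its value was 5.17 without glycerol replicate 1 and 1.87 without glycerol replicate 2. It did not pass without glucose replicate 1 or 2 (higher adjusted p = 0.128). HSP26, a small heat shock protein, had 59.5 CPM in glycerol replicate 1 and 952 in replicate 2 and did not pass (3.13, SE 1.12, adjusted p = 0.0682). Of 6 markers of quiescent or stationary-phase cells 2 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0244; adjusted p = 0.508 with an estimated correlation). Their share of counts was 0.0311% in glycerol replicate 1 and 0.374% in replicate 2. In glycogen metabolism 6 of 7 rose (7 adjusted over the list alone; adjusted p = 0.0599 with an estimated correlation), with GLC3, the branching enzyme, at 3.02 (SE 0.330). In trehalose synthesis and breakdown 6 of 7 rose (7 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation), with ATH1, the acid trehalase, at 2.74 (SE 0.445) and TPS1, trehalose-6-phosphate synthase, at 1.58 (SE 0.285). Of 17 vacuolar protease and autophagy genes 10 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 0.294 with an estimated correlation). ATG34, an autophagy receptor with 0 counts on glucose, was at least 7.91-fold higher. Its fitted log2 value, which depends on the prior count, was 7.85, and 6.49 without glycerol replicate 2.

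Hexose transporters divided on glycerol, with 3 of 5 fallen and 1 risen (3 and 1 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation). HXT3 went from 489 ± 117 to 16.6 ± 11.5 CPM (log2 fold change -5.03, SE 0.448) and HXT1 changed by -4.80 (SE 0.486), whereas HXT5, a transporter of slowly growing cells, rose by 3.70 (SE 0.876). Without glycerol replicate 1 HXT3 and HXT1 were at -4.28 and -4.11, and without glycerol replicate 2 at -5.79 and -5.41. HXT5 had 279 CPM in glycerol replicate 1 and 2867 in replicate 2. Without glycerol replicate 1 its value was 4.57, and without glycerol replicate 2 it was 1.21. Without glucose replicate 1 or 2 it did not pass (higher adjusted p = 0.112). Of 19 genes of glycolysis and ethanol formation 3 rose and 4 fell (4 and 7 adjusted over the list alone), with TDH1, a glyceraldehyde-3-phosphate dehydrogenase, at 3.19 (SE 0.548) and PDC1 at -1.46 (SE 0.276), and the list, with a median of -0.34 and a mean of 0.21, did not shift (camera adjusted p = 0.501). TDH1 was at 3.85 without glycerol replicate 1 and at 1.95 without glycerol replicate 2.

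Ribosomal protein genes were lower, 69 of 88 having fallen and 0 risen (77 and 0 adjusted over the list alone), with a median log2 fold change of -1.26 (camera adjusted p = 4.69e-29; adjusted p = 0.0599 with an estimated correlation). RPS9B changed by -2.36 (SE 0.411) and RPS3 by -0.93 (SE 0.257), while RPL3, with 9125 CPM in glycerol replicate 1 and 5368 in replicate 2, did not pass (-0.70, SE 0.267, adjusted p = 0.0850). Of 106 ribosome biogenesis genes 53 fell and 0 rose (72 and 0 adjusted over the list alone; adjusted p = 0.0672 with an estimated correlation), NSR1 at -1.66 (SE 0.257). Of 28 translation factors 12 fell (18 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation), and of 21 RNA polymerase subunits 8 fell (9 adjusted over the list alone; adjusted p = 0.0883 with an estimated correlation), RPA135 at -1.47 (SE 0.245). Of 35 Gcn4 targets 21 fell and 0 rose (26 and 0 adjusted over the list alone; adjusted p = 0.0437 with an estimated correlation), ARG3 at -4.25 (SE 0.300) and HIS4 at -2.72 (SE 0.262). PMA1, the plasma membrane proton pump, fell by 1.23 (SE 0.237), and ACT1, actin, had a value of -0.18 (SE 0.223, adjusted p = 0.592).

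In all, 743 genes passed, 383 higher and 360 lower on glycerol (187 and 377 by limma-voom, 446 and 294 with library totals), with 1172 at an unadjusted p under 0.05, and 21 of 31 lists shifted with camera's preset correlation against 1 with an estimated correlation. Without glucose replicate 1 the count was 64, without glucose replicate 2 it was 249, without glycerol replicate 1 it was 1123 and without glycerol replicate 2 it was 811. Of the 108 named genes that passed, 21 were past the threshold in all 8 fits that left out a library, among them CAT2, POX1, FOX2, CIT1, GUT2, GLC3, HXT1, HXT3, ARG3, HIS4 and NSR1. The fold change of 47 of the 108 moved by over 1.5 times on leaving out some library, of 31 without glycerol replicate 1 and of 30 without glycerol replicate 2.

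Growth on trehalose, a disaccharide of glucose, was compared with growth on glucose to ask how translation differs on a sugar that yeast must first cleave. Stress and storage genes were higher on trehalose: all 21 tested general stress genes rose (21 adjusted over the list alone), with a median log2 fold change of 3.93 (camera adjusted p = 9.61e-13; adjusted p = 0.269 with an estimated correlation). HSP26 (YBR072W) went from 56.4 ± 15.9 to 1823 ± 225 CPM (SE of the log2 fold change 1.15, adjusted p = 0.00806). Without glucose replicate 1 or 2 HSP26 did not pass (higher adjusted p = 0.0712). CTT1 went from 29.5 ± 6.18 to 1289 ± 179 CPM (5.44, SE 1.06). HSP12, another stress gene, had 0 counts in every library and was not tested.

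The enzymes of trehalose itself were higher, 6 of 7 having risen and 0 fallen (7 and 0 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation). ATH1 went from 29.5 ± 6.18 to 421 ± 97.1 CPM (3.81, SE 0.439, adjusted p = 0.000365), NTH1, the neutral trehalase, from 155 ± 0.616 to 678 ± 32.8 CPM (2.13, SE 0.377), and TPS1 from 351 ± 42.9 to 1736 ± 82.5 CPM (2.30, SE 0.291). In glycogen metabolism 6 of 7 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.0818 with an estimated correlation), GLC3 by 3.87 (SE 0.334) and GDB1, the debranching enzyme, by 3.68 (SE 0.489). The markers of quiescent or stationary-phase cells rose in 6 of 6 tested cases (6 adjusted over the list alone; adjusted p = 0.404 with an estimated correlation). Among them GRE1 changed by 4.32 (SE 0.972), and XBP1, a transcriptional repressor with 0 counts on glucose, was at least 9.86-fold higher. The fitted log2 value of XBP1, which depends on the prior count, was 7.79, and 7.18 without trehalose replicate 1. HSP26, GRE1 and SPI1 are in both the stress and the quiescence list.

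Peroxisomal beta-oxidation had 10 of 11 genes risen and 0 fallen (10 and 0 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation), POX1 at 5.01 (SE 0.577) and POT1 at 4.33 (SE 0.674). In the glyoxylate and gluconeogenesis list 10 of 19 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 0.404 with an estimated correlation), with ACS1, acetyl-CoA synthetase, at 3.95 (SE 0.568), PCK1 at 2.32 (SE 0.735) and ICL1 at 2.45 (SE 0.668; 3.16 without glucose replicate 2), while FBP1 did not pass (adjusted p = 0.522). Of 11 respiratory chain genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.404 with an estimated correlation). Of 13 TCA cycle genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), and that list did not shift (camera adjusted p = 0.0695). Of 17 vacuolar protease and autophagy genes 12 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 0.282 with an estimated correlation). ATG34 was at least 17.7-fold higher than on glucose, where it had 0 counts.

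Sugar transport and glycolysis changed gene by gene. HXT1, with 2 counts over the trehalose libraries against 97 on glucose, was 115-fold lower (95% counting interval 30.9 to 961). Its fitted log2 fold change was -6.67, and -9.42 without trehalose replicate 1. HXT3 went from 489 ± 117 to 6.33 ± 2.47 CPM (log2 fold change -6.03, SE 0.520, and -6.63 without trehalose replicate 1). HXT5 went from 121 ± 13.6 to 3965 ± 907 CPM (5.03, SE 0.917) and HXT2, a high-affinity transporter, rose by 0.93 (SE 0.302), so that 2 of 5 rose and 2 fell (2 and 3 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). HXT2 did not pass when any 1 of the glucose, galactose or trehalose libraries was left out (highest adjusted p = 0.192). In glycolysis and ethanol formation 5 of 19 genes rose and 7 fell (5 and 7 adjusted over the list alone), TDH1 at 4.31 (SE 0.569), HXK1 at 3.86 (SE 0.442) and ENO1, an enolase, at 3.13 (SE 0.470), against HXK2 at -1.14 (SE 0.254) and CDC19 at -0.81 (SE 0.237). The list as a whole, with a median of -0.34 and a mean of 0.45, did not shift (camera adjusted p = 0.963). GAL2, at -0.98 (SE 0.533, adjusted p = 0.175), GAL7 and GAL10 did not pass.

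The translation machinery was lower on trehalose. Of 88 ribosomal protein genes 84 fell and 0 rose (85 and 0 adjusted over the list alone), with a median log2 fold change of -1.77 (camera adjusted p = 1.52e-31; adjusted p = 0.0594 with an estimated correlation). RPL3 went from 11790 ± 868 to 4192 ± 222 CPM (-1.49, SE 0.272), RPS3 changed by -1.83 (SE 0.263) and RPL40A by -2.67 (SE 0.282). Of 106 ribosome biogenesis genes 69 fell and 0 rose (81 and 0 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation), NOP1, the rRNA methylase fibrillarin, at -1.99 (SE 0.288) and NSR1 at -1.93 (SE 0.264). Of 28 translation factors 18 fell and 0 rose (20 and 0 adjusted over the list alone; adjusted p = 0.148 with an estimated correlation), including YEF3, elongation factor 3, at -2.23 (SE 0.296). TEF1, at -0.95 (SE 0.381), did not pass (adjusted p = 0.0755). Of 21 RNA polymerase subunits 13 fell and 0 rose (16 and 0 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation).

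Amino acid synthesis was lower as well. Of 35 Gcn4 targets 30 fell and 0 rose (31 and 0 adjusted over the list alone; adjusted p = 0.0594 with an estimated correlation), ARG1 at -4.22 (SE 0.318) and ASN1 at -3.48 (SE 0.254). In methionine synthesis and sulfate assimilation 6 of 9 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.166 with an estimated correlation), SAM1, an S-adenosylmethionine synthetase, from 2381 ± 139 to 96.5 ± 32.9 CPM. PMA1 changed by -1.82 (SE 0.241) and ACT1 by -0.41 (SE 0.223, adjusted p = 0.177). MCM16, a kinetochore gene, had a log2 fold change of -7.35 (SE 0.973), but its glucose libraries held 3280 and 870 CPM. It belongs to 8 tested genes that had at least 50 counts in glucose replicate 1, were over 3-fold higher there than in glucose replicate 2, and whose median tracked the unmapped reads between replicates on the other carbon sources. MCM16 was at -6.13 without glucose replicate 1 and -8.07 without glucose replicate 2, and without trehalose replicate 1 no count was left on trehalose. MRPL7, a mitochondrial ribosomal protein gene, changed by -4.67 (SE 0.658) with 2882 ± 1712 CPM on glucose, and by -3.92 without glucose replicate 1 and -5.49 without trehalose replicate 1.

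In all, 1189 genes passed, 600 higher and 589 lower on trehalose, with 1507 at an unadjusted p under 0.05, and 18 of 31 lists shifted with camera's preset correlation against 0 with an estimated correlation. The count was 609 without glucose replicate 1, 667 without glucose replicate 2, 688 without trehalose replicate 1 and 771 without trehalose replicate 2. Of the 123 named genes that passed, 77 were past the threshold in every fit that left out a library and tested them. The fold change of 23 of the 123 moved by over 1.5 times on leaving out some library: 8 and 9 without glucose replicates 1 and 2, and 13 and 2 without trehalose replicates 1 and 2.

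**Figure D4:**
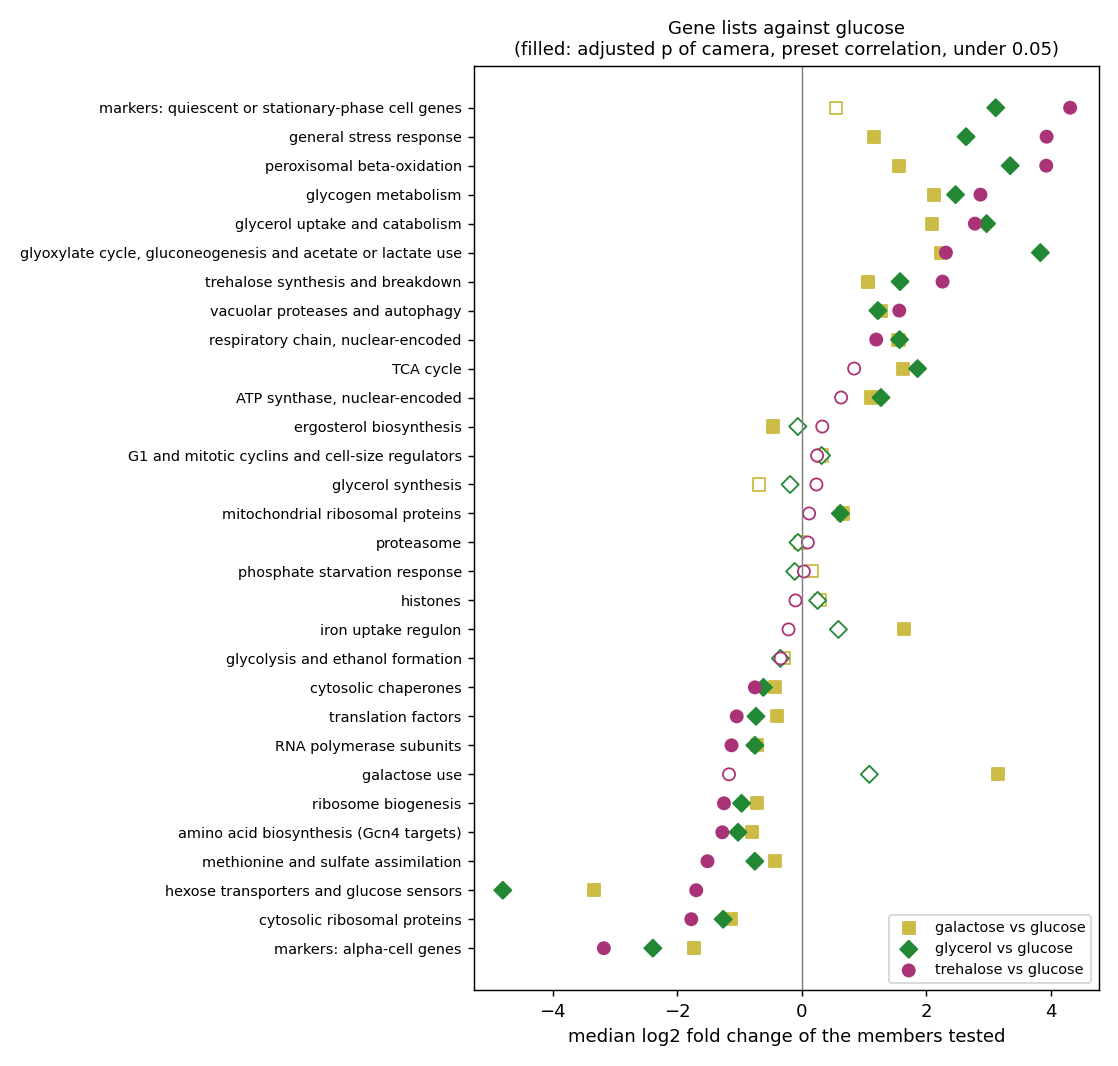
Median log2 fold change against glucose of the tested members of 30 gene lists, squares for galactose, diamonds for glycerol and circles for trehalose, filled where camera's adjusted p with the preset correlation was under 0.05. Ribosomal proteins lie at -1.14, -1.26 and -1.77, and general stress genes at 1.17, 2.64 and 3.93, in that order; most of the filled points were not past 0.05 with an estimated correlation.

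Among the carbon sources other than glucose, trehalose differed from galactose at 499 genes, 257 higher and 242 lower on trehalose. GAL2 went from 8147 ± 124 CPM on galactose to 219 ± 187 on trehalose (log2 fold change -5.15, SE 0.602, adjusted p = 0.00104) and GAL10 from 1043 ± 249 to 26.8 ± 24.9 CPM (-4.99, SE 0.566). SSA3, a stress-induced chaperone of the HSP70 family, rose by 4.79 (SE 1.01), and ECM10, a mitochondrial HSP70, had 0 counts on galactose and was at least 11.4-fold higher on trehalose. SSA3 and ECM10 did not pass when any 1 of the galactose or trehalose libraries was left out (highest adjusted p = 0.134 and 0.156), and SSA3 was at 5.53 without galactose replicate 2. GAL2 was at -6.54 and -4.53 without trehalose replicates 1 and 2, and GAL10 had 2 counts left on trehalose without replicate 1. Of the 8 named genes 6 moved by over 1.5 times in fold on leaving out some library. The count was 316 without glucose replicate 1 and 331 without glucose replicate 2, 64 and 115 without galactose replicates 1 and 2, 1036 and 1035 without glycerol replicates 1 and 2, and 56 and 89 without trehalose replicates 1 and 2.

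Glycerol differed from galactose at 9 genes, all lower on glycerol, against 450 at an unadjusted p under 0.05. FIT2 changed by -2.63 (SE 0.332), FIT3 by -2.33 (SE 0.243), SCW10, a cell wall glucanase, by -2.26 (SE 0.316) and GIC2, an effector of the polarity GTPase Cdc42, by -2.01 (SE 0.278). That direction depends on the setting. DESeq2 called 54 genes, 26 higher and 28 lower on glycerol, and limma-voom 31, 3 higher and 28 lower. With no filter edgeR called 252, 178 higher and 74 lower, and on the 4 libraries of these carbon sources alone it called 0. Without galactose replicate 1 the count was 0, without glycerol replicate 1 it was 430 (279 higher and 151 lower), without glycerol replicate 2 it was 172 (84 higher and 88 lower), and without trehalose replicate 1 or 2 it was 3.

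Trehalose differed from glycerol at 6 genes, all lower on trehalose, against 505 at an unadjusted p under 0.05. FIT3 changed by -2.59 (SE 0.273, adjusted p = 0.00821), SAM1 by -2.40 (SE 0.361), UTR2, a cell wall glycosidase, by -2.39 (SE 0.377) and FET3, the multicopper oxidase of iron uptake, by -2.34 (SE 0.367). Without glycerol replicate 1 SAM1, UTR2 and FET3 were at -1.82, -1.66 and -1.72, each over 1.5 times smaller in fold. DESeq2 called 36 genes, 2 higher and 34 lower, limma-voom 4, all lower, and edgeR with no filter 275, 120 higher and 155 lower. Without glycerol replicate 2 the count was 848, 454 higher and 394 lower on trehalose, and without glycerol replicate 1 it was 55 (2 higher and 53 lower), while it was 0 without either glucose library, either trehalose library or galactose replicate 2 and 1 without galactose replicate 1.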

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

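The test of depth was chosen before its result was seen, and the tests of a wrong label and of a mixture after the libraries had been compared. Sequences with no gene name were not removed before testing. They are in the library totals and, where they passed the filter on low counts, among the genes tested. With no filter, all of them with a count were tested. The share of counts on sequences with no gene name had a mean of 0.0662% on trehalose (0.0704% and 0.062%), above both glucose libraries (0.0546% and 0.0334%). It was 0.0251% and 0.127% in the glycerol libraries.

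The glycerol libraries differed more than the replicates of any other carbon source, and glycerol replicate 2 lay toward trehalose. Unequal depth is argued against: with all libraries thinned to 184589 counts, the coefficient of variation was 0.362 between the glycerol libraries and 0.128, 0.162 and 0.137 between those of glucose, galactose and trehalose. A trehalose library under a wrong label stays open, since glycerol replicate 2 was short of the other trehalose library's position by 0.0919 (95% interval 0.0713 to 0.135) on 1 scale, within the 0.1 set for a match, and by 0.186 (0.156 to 0.2) on the other. A mixture of glycerol-like and trehalose-like material cannot be told apart from it, since the trehalose-like share from genes higher in trehalose and that from genes lower differed by -0.0282 (-0.128 to 0.0595) and 0.148 (-0.00992 to 0.385), intervals that include 0. A real difference between cultures, such as a later growth stage, may also account for it and was not tested.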

How the results depend on the processing

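Leaving out both glycerol libraries, and both blocks fitted to glycerol and trehalose alone, were chosen after seeing the data. Of 321 values of a named gene in a comparison that were past the threshold, 304 were past it under every scaling tried and 101 in every fit that left out a library and tested them. Against glucose, the genes higher and lower were 76 and 113 (galactose), 187 and 377 (glycerol) and 363 and 579 (trehalose) by limma-voom, and 136 and 94, 446 and 294, and 676 and 523 with library totals. Library totals moved the median of all genes by 0.108 (glycerol against glucose) and 0.11 (trehalose against glucose) on the log2 scale. Counts with no filter were 439 for galactose against glucose, 252 for glycerol against galactose and 275 for trehalose against glycerol. With the strict filter they were 784 for trehalose against glucose and 1 for trehalose against glycerol, with fewer genes tested (1369). With only the 2 groups compared, the 4 libraries gave 570, 455 (glycerol against glucose), 0, 990 (trehalose against galactose) and 0. With a minimum fold change of 1.5 they were 42, 373, 2, 193 and 1. For glycerol against galactose and trehalose against glycerol, library totals gave 4 and 1, DESeq2 54 and 36, robust estimation 30 and 15, and the replicate block 3 and 1, and limma-voom gave 31 for the former. Without both glycerol libraries the counts were 617 for galactose against glucose (240 shared with the 241), and 1012 for trehalose against galactose. Leaving out single libraries aside, all other planned settings stayed within 1.5 times the count of genes. Each comparison that does not involve glycerol gained genes when glycerol's libraries, which had the widest spread, were left out of the shared estimate. For the other differences, except for fewer genes or libraries, the cause was not tested.

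Replicate numbers were not used to pair libraries. Over the 6 pairs of carbon sources, the correlation of replicate deviations was 0.125 (galactose with trehalose), 0.111 (glucose with galactose), 0.089 (galactose with glycerol), 0.027 (glucose with trehalose), -0.034 (glucose with glycerol) and -0.216 (glycerol with trehalose). The last value could reflect crossed numbers, and the crossed block and the plain block each called 0 genes on those 4 libraries. With the block the counts were 209, 683, 1161, 3, 508, 1 and, among all carbon sources, 898. Lists shifted in 5 cases (galactose), 1 (glycerol) and 0 (trehalose) with an estimated correlation. The test fry, which asks whether a list's genes move at all and not whether they differ from other genes, passed 15 lists in its directional form for galactose and 29 in its mixed form, which has no direction, for trehalose. Lists that differed in share numbered 0 when permuted within replicate number, where an exact p cannot go below 0.04167.

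Leaving out each library in turn gave 1 to 620 genes for galactose against glucose, 64 to 1123 for glycerol against glucose, 609 to 1517 for trehalose against glucose, 0 to 430 for glycerol against galactose, 56 to 1036 for trehalose against galactose, 0 to 848 for trehalose against glycerol and 347 to 1608 among all. The lone library of a carbon source is there assumed to vary like the others. Shares gave 0 to 25 lists. The test across all 4 carbon sources has no value for only the 2 groups compared or for a minimum fold change. Settings without near-identical copies were not run, since no genome was used, and pseudocounts did not apply to counts. Low depth limits single genes at 0 to 3 counts, given as bounds or with intervals.

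Signs reversed only for values that did not pass the test and, the fits without a library aside, only in the lists named next. Glycolysis on trehalose was up by fry (adjusted p = 0.9268), with library totals (0.9846) and with the replicate block (0.9848), and cyclins on trehalose were up by fry (0.9749). Over the fits that left out a library, log2 fold changes on galactose ran from -0.194 to 2.889 for FBP1 and from -1.385 to 1.215 for HSP26, each lowest without galactose replicate 2 and highest without galactose replicate 1, and from -0.454 to 0.13 for TEF1, without glucose replicates 1 and 2. On glycerol they ran from -0.386 to 0.01 for ACT1, from -0.541 to 0.03 for HXK2 and from -0.917 to 0.341 for TEF1, without glycerol replicates 1 and 2, and TEF1 passed in the former. XBP1 had 0 counts on glucose and in galactose replicate 1, so its fitted values on galactose (0 without galactose replicate 2, 5.534 without galactose replicate 1) depend on the prior count and are neither folds nor a reversal. Adjusted p-values of lists with a reversal (camera) ran on glycerol from 0.1415 to 0.6337 for glycolysis, 0.5618 to 0.8419 for glycerol synthesis, 0.02402 to 0.8667 for ergosterol (down and past 0.05 without glycerol replicate 2), 0.3723 to 0.9531 for the proteasome, 0.3746 to 0.8667 for histones and 0.7758 to 0.9702 for cyclins. On trehalose they ran from 0.4619 to 0.9752 for glycolysis, 0.727 to 0.9656 for mitochondrial ribosomal proteins and 0.5379 to 0.9581 for cyclins.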

Other observations

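The tests of unmapped reads and of shared flanks below were chosen after the results were seen. Genes of the alpha mating type were lower on every other carbon source than on glucose: of 4 tested, 2 fell on galactose, 3 on glycerol and 4 on trehalose, and 0 rose (4, 4 and 4 fell adjusted over the list alone; camera adjusted p = 7.06e-07, 2.6e-06 and 2.55e-05; adjusted p = 0.0417, 0.0599 and 0.0818 with an estimated correlation). MF(ALPHA)2, a mating pheromone, went from 1120 ± 137 CPM on glucose to 207 ± 56.2, 66.8 ± 38.9 and 24.6 ± 8.94 (mean ± SD, n = 2), and SAG1, the alpha agglutinin, from 351 ± 107 to 30.6 ± 2.27, 26.9 ± 9.55 and 11.3 ± 3.04. Of 4 haploid genes 3 fell on trehalose (3 adjusted over the list alone; camera adjusted p = 0.0874), 1 fell on glycerol, and on galactose FAR1 rose while GPA1 fell. The a-cell genes, none of which had enough counts to be tested, took 0.000934% of counts on glucose and 0.00202% on trehalose. BAR1 held the most of them, 22 counts over all 8 libraries, so this difference rests on few counts.

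Of 21 cytosolic chaperone genes 10 fell on trehalose and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.00210; adjusted p = 0.128 with an estimated correlation). The list's share of counts was 2.18% ± 0.0661 on glucose and 2.09% ± 0.123 on trehalose (exact permutation test across the 4 carbon sources, p = 0.429, adjusted p = 0.455). SSA2, an HSP70 chaperone, fell by 3.23 (SE 0.243) on the log2 scale and its close homologue SSA1 rose by 1.63 (SE 0.251). Reads that these 2 genes share could be lost or misplaced, and sequence in common was not checked, so their single values are uncertain. Of 18 ergosterol genes 6 rose on trehalose (4 adjusted over the list alone), ERG3 by 2.63 (SE 0.487), and the list did not shift (camera adjusted p = 0.166). Its share of counts was 0.889% ± 0.0824 on glucose, 2.52% ± 0.0528 on trehalose, and 0.685% and 1.79% in the glycerol libraries (exact permutation test across the 4 carbon sources, adjusted p = 0.0933). Of 27 genes of the proteasome list 2 rose on trehalose (1 adjusted over the list alone). They were RPN4, which encodes a transcription factor of proteasome genes and no subunit, by 2.74 (SE 0.361), and the subunit gene RPN11, past the threshold in 2 of the 8 fits that left out a library. Of 8 histone genes 3 fell (3 adjusted over the list alone), HTB2 among them at -1.08 (SE 0.285). Neither the proteasome nor the histone list shifted (camera adjusted p = 0.554 and 0.524). In glycerol synthesis GPD1 rose on trehalose by 2.51 (SE 0.305) and GPP1 changed by -1.58 (SE 0.442). Of 8 phosphate genes 2 rose on trehalose (2 adjusted over the list alone), and PHM8, with 1 count on glucose, was 85.8-fold higher (95% counting interval 15.2 to 3405). The fitted log2 fold change of PHM8 was 6.28, and 5.38 and 9.53 without glucose replicates 1 and 2. Of 11 cyclin and cell-size genes BCK2 rose on trehalose and CLB2 fell (0 and 0 adjusted over the list alone). Each was past the threshold in 3 of the 8 fits that left out a library. Neither passed without glucose replicate 1 or 2, galactose replicate 1 or trehalose replicate 1, BCK2 did not without trehalose replicate 2, and CLB2 did not without galactose replicate 2. This is a list with a positive median (0.25) and a camera direction that was down (adjusted p = 0.961).

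Of 35 mitochondrial ribosomal protein genes 3 rose on galactose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.378 with an estimated correlation). On trehalose 0 rose and 1 fell, with a median of 0.12, a mean that was -0.003 and no shift (camera adjusted p = 0.961). Mitochondrially encoded genes took 0.00047% of counts on glucose, alpha-glucoside genes 0.00773% on glucose and 0.016% on trehalose, and meiosis and sporulation markers 0.00305% ± 0.000283 and 0.0155% ± 0.00145.

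The tested genes with at least 50 counts in glucose replicate 1 and over 3-fold higher CPM there than in glucose replicate 2 were the 8 genes SLM3, TAO3, VID28, GTT2, PRM6, NTG2, TIR2 and MCM16, chosen after their values were seen. Glucose replicate 1 had 10.66% of its reads unmapped and glucose replicate 2 had 3.21%. On 3 of the 3 other carbon sources their median ratio, of the library with more unmapped reads to the other, lay above random lists matched on expression (2.24 on galactose, 2.18 on glycerol, 1.38 on trehalose; percentiles 100, 99.98 and 99.71). The random lists were of genes drawn singly, so these percentiles do not allow for genes that move together. On trehalose the unmapped shares were close, 0.91% and 0.71% in replicates 1 and 2. Fragments that come and go with the unmapped reads may make up part of these genes' counts, VID28 and its 19060 CPM in glucose replicate 1 included. No biological explanation was tested.

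Genes with no count in any library included GAL1, HSP12 and HXT7. Of 1169 genes without a base free of their same-strand neighbours' flanks 80.2% were at 0, against 4.7% of 4432 genes with over 200 free bases and 5.7% of 1286 genes covered on the opposite strand alone. Uncounted reads that match more than 1 reference sequence are a candidate explanation for most of these zeros. GAL1, HSP12 and HXT7 have free bases (1422, 330 and 1302), so flanks shared with named genes do not account for their zeros. Free bases were counted against named genes only. Overlap with sequences that have no gene name, and near-identical copies, were not tested and stay open.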
